A study of Mus musculus with 1000 samples.

How the data were processed

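The series comprised 1000 RNA libraries, each from the brain of a different mouse. Per the labels' protocols, founder C57BL/6NCrl males, an inbred black mouse substrain, received 3 doses of 100 mg/kg ENU, a chemical that mutates the germ line. The mutations were then bred to homozygosity over 3 generations. Siblings of generation 3 still differed in genotype where the labels give it for a whole family. Mice of generation 3 were usually 8 to 12 weeks old at collection. The cerebellum was removed and the rest of the brain was kept in a preservative for up to 5 days. Per the labels' protocols, libraries were made with a SMART-Seq v4 3' kit, which reads the 3' end of each transcript, from 4 ng of total RNA with 8 cycles of amplification. Each sample of a plate row received its own in-line index, the 12 samples of a row were mixed as 1 cDNA pool, and 96 such pools from 12 plates formed a sequencing library of 1152 samples. Per the submitters' processing notes, GSNAP and the genome build GRCm38 were used. The version of GSNAP, the read counting and the normalization are not given in the sources used here.

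The processed file analysed here was the authors' lookup table, and it held no measurement. It listed 23231 library names, each with 1 of 3 names for the part of the processed data that holds that library's values. Expression values were not analysed here, so no read count, sequencing depth, gene level or fold change is reported and the precision of such values is unknown. The comparisons of gene expression fixed before the data were examined (Ctsd m/m and m/+ animals against +/+ siblings, and Mff m/m animals against siblings of unstated genotype, each for genes past an adjusted p of 0.05) need those values and were not run. The rule for named genes allowed, in that case, only the genes that the labels name, Ctsd and Mff. Of the listed libraries, 22231 were outside this series and were not used.

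Groups were taken from the labels: the gene and amino acid change, the genotype and the Unaffected label for 32 libraries, and membership outside that labelled subset for the other 968. Each library name was split into an ENU number, an animal number, a well, a plate number and an S number. The ENU number was read as the family, because each gene label stood on 1 ENU number. The S number was read as the index of the cDNA pool, and this reading was checked: all 86 plate rows had 1 S number each, and on all 17 plates the S number was the rank of the row plus a multiple of 8.

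Samples were looked up by exact name. Nesting of families in pools was counted and set beside 10000 random reassignments of the libraries to the same wells. Numbers of animals carrying the phenotype label were compared between genotypes with a two-sided Fisher's exact test by full enumeration, with a threshold of 0.05. An empty phenotype label was counted as label absent, which does not mean that the animal was scored as normal. The labelled amino acid changes were placed on the GENCODE M21 annotation of GRCm38 by translating the complete coding transcripts of both genes. Positions of residues count from the initiator methionine and positions of bases from the A of the start codon. The counting routines passed 5 of 5 checks on simulated layouts and tables with known answers. Alternatives covered the definition of a pool, the families entering, the matching of names, the grouping of genotypes and the omission of each animal in turn. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 were used.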

Results

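Brain RNA libraries from 1000 third-generation offspring of ENU-treated mice were examined through their labels and a lookup table of library names. The 1000 animals fell into 94 families. Of these, 3 families with 32 animals carried further labels, and the animals of the other 91 families were labelled only with tissue and as outside this subset. The labelled families were a Mff V297D family of 12 animals, a Ctsd T263A family of 8 animals and a family of 12 animals labelled Unaffected. Mff encodes mitochondrial fission factor, an outer-membrane protein that recruits the fission GTPase to mitochondria. Ctsd encodes cathepsin D, a lysosomal aspartic protease. The series' design text states that the RNA-seq data were searched for abnormal inflammation states and that exome sequencing was used to find candidate causal variants. Gene expression was not analysed here, so no difference in the level of any gene is reported and the sequencing depth of the libraries is unknown.

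The first comparison the labels allow is of phenotype with genotype within a family. In the Mff family, the phenotype label DAM, an abbreviation that the labels do not spell out, stood on 2 animals, and both were m/m. Both of these animals also had a histology block, block 7. The other 10 Mff siblings had no phenotype label, no genotype and no histology block. The difference between 2 of 2 and 0 of 10 gave p = 0.0152 in a two-sided Fisher's exact test, which is the smallest p that 12 animals with 2 labels can give. Because a genotype was stated only for the 2 animals with the phenotype label, this test compares animals with and without a stated genotype, not mutant with wild-type animals. Its p was fixed by which animals had a stated genotype and is no evidence for an effect of the genotype.

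In the Ctsd family, the phenotype label stood on heterozygous animals. It was carried by 2 of 4 m/+ animals, by 0 of 2 m/m animals and by 0 of 2 +/+ animals. The histology block label, block 5, was instead on both m/m animals and on no m/+ or +/+ animal. The phenotype label did not differ detectably between the 3 genotypes (two-sided Fisher's exact test, p = 0.429), and with 2 labels among these 8 animals the test of 3 genotypes cannot give a p below 0.0714. Of the 8 genotyped animals, 2 were m/m, 4 were m/+ and 2 were +/+. The Unaffected family had 12 animals, none with a genotype, phenotype or histology label.

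**Figure D1:**
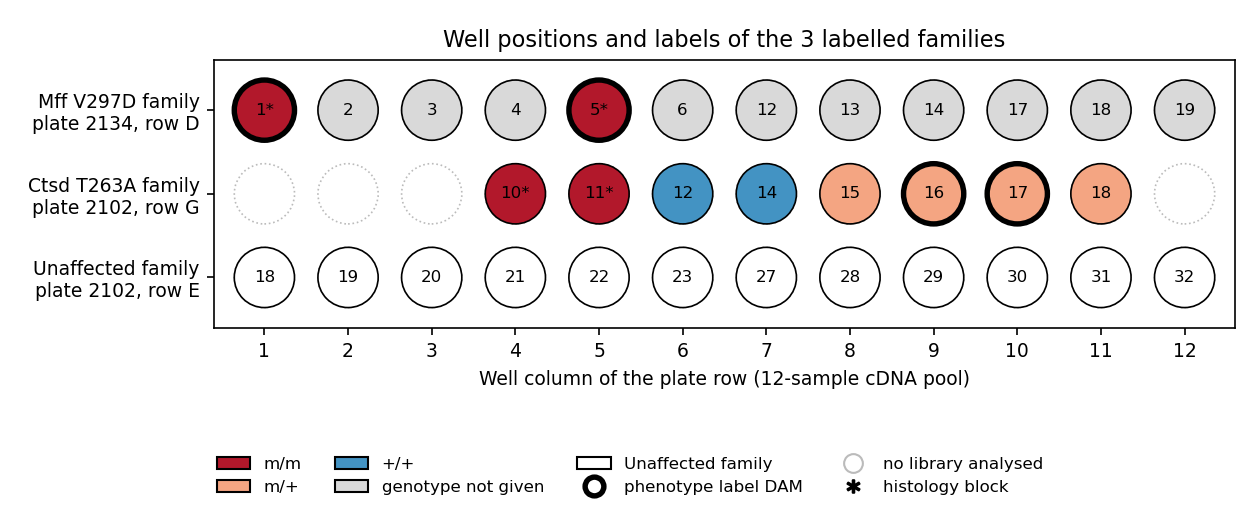
Plate-row positions of the 3 labelled families, with the well column on the horizontal axis, 1 row of circles per family and the animal number inside each circle. Fill gives the genotype, a heavy outline the phenotype label DAM and an asterisk a histology block. Phenotype labels are on the 2 m/m animals of the Mff family and on 2 of the 4 m/+ animals of the Ctsd family.

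The labelled changes were then placed on the annotation. Mff (ENSMUSG00000026150.14) lies on the plus strand of chromosome 1 from 82724890 to 82752394 in GRCm38. The residue Val297 occurs in 1 of its 6 complete coding transcripts, Mff-212, which GENCODE tags as not organism supported. Its codon GTC lies in exon 11 of 11, at 82751654 to 82751656. All 6 transcripts contain this codon in frame, in their last exon. In Mff-202, the principal isoform, the same residue is Val272. In the other 4 transcripts it is Val199, Val219, Val220 and Val224. The labels do not name the transcript that the numbering follows, so this position rests on the GENCODE M21 numbering. The codon stands 0.738 kb before the annotated 3' end of Mff-212 and 0.734 kb before that of Mff-202. The surrounding coding sequence of Mff-212, with 15 bases on each side of the codon, is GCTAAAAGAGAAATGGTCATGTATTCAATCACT. A single base substitution turns this valine codon into one for aspartate, T890A.

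Ctsd (ENSMUSG00000007891.16) lies on the minus strand of chromosome 7 from 142375911 to 142388038. Both of its complete coding transcripts have the residue Thr263, in exon 6 of 9. The codon ACT occupies 142377365 to 142377367 and stands 1.104 kb before the annotated 3' end of the principal isoform, Ctsd-202, which encodes 410 residues. The DTG motifs that mark the catalytic aspartates of this protease family start at Asp97 and Asp293, on either side of the labelled residue. The coding sequence with 15 bases on each side of the codon is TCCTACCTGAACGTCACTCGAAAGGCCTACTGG in Ctsd-202. A single base substitution gives an alanine codon, A787G. The labels give the amino acid changes only, so the base changes of both genes are the sole single-base routes in the genetic code, not observed variants.

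**Figure D2:**
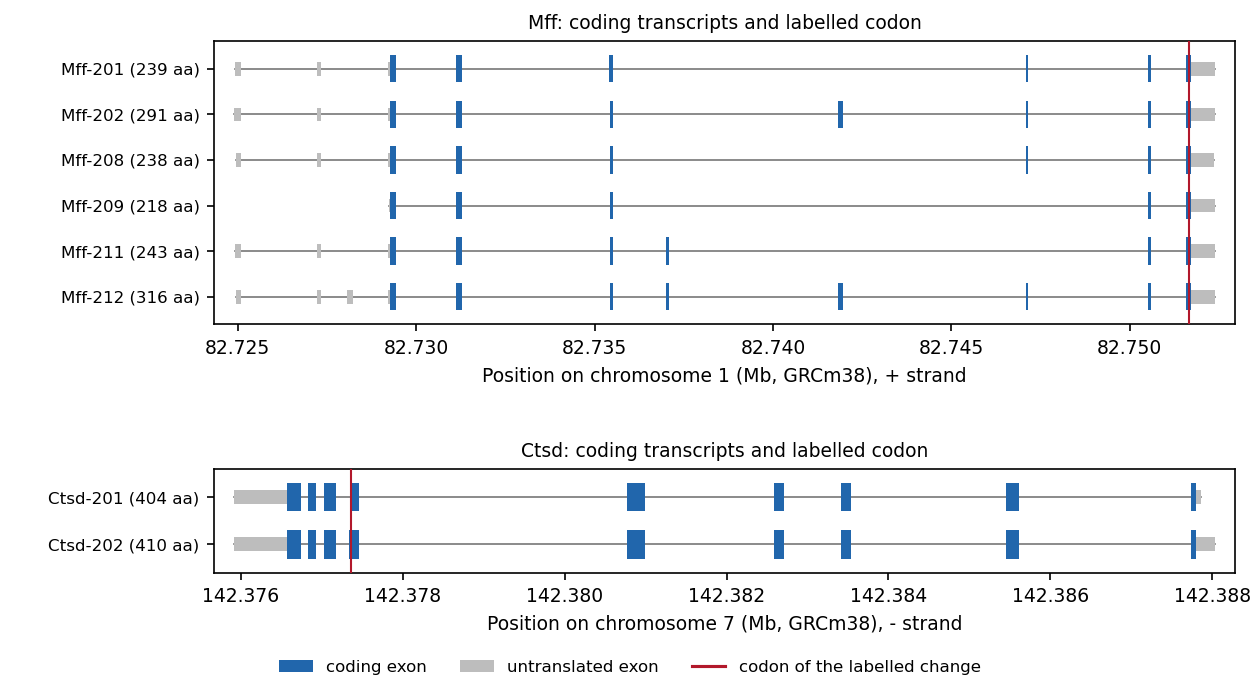
Complete coding transcripts of Mff and Ctsd along their chromosomes in Mb of GRCm38, with coding exons in blue, untranslated exons in grey and the codon of the labelled change as a red line. The Mff codon lies in the last exon of all 6 transcripts, and the Ctsd codon in exon 6 of 9 in both.

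Comparisons between families depend on how libraries were pooled. Among the 1000 libraries of this series, every one of the 94 families lay within 1 cDNA pool, that is, within 1 row of 1 plate. The listed libraries outside this series were not searched for further siblings. None of 10000 random reassignments of libraries to the same wells put any family in a single pool. Of the 86 pools, 78 held 1 family and 8 held 2 families. All 3 labelled families were the only family of their pool among these libraries, so family and pool cannot be told apart for them. The Ctsd row had 8 libraries here, and its other 4 wells were not analysed. The Ctsd and Unaffected families shared a plate but not a pool, and the Mff family was on another plate, with 6 unlabelled families. Siblings within a family shared their pool, so genotypes within the Ctsd or Mff family are not separated by pool. Within the Ctsd pool, however, each genotype occupied its own stretch of columns, with m/m in columns 4 and 5, +/+ in columns 6 and 7 and m/+ in columns 8 to 11.

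Families had a median of 12 libraries in this series, the number of siblings the protocol gives as typical. The range was 6 to 12: 72 families had 12 libraries, 2 had 8 and 20 had 6. No animal was represented by more than 1 library of this series. All 1000 libraries were found by exact name in the lookup table, and all 1000 were assigned to the first of its 3 parts.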

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

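The exact test of the Ctsd label across 3 genotypes and the grouping of carriers were planned before the lookup table was examined, with the labels known; the other tests in this part were chosen after the result was seen. The phenotype labels of the 2 mutant families stood on different genotypes: both labels of the Mff family were on m/m animals, and both labels of the Ctsd family were on m/+ animals. This was singled out as a difference between the families, but Fisher's exact test of the difference gave p = 0.333. That is the smallest p that 4 labels can give with 2 in each family and 2 of the 4 on m/m animals. Moreover, in the Mff family a genotype is stated only for the 2 animals with the label, so its labels could stand on no other stated genotype. A difference between the families is therefore not shown. A phenotype label that marks recessive effects of Ctsd T263A is argued against by the labels as they stand, since 2 m/+ animals carried it. The same labels give no support to an effect of dosage, since 0 of 2 m/m animals carried it. An empty label is not a score of normal, however, and the histology blocks of this family stood on its 2 m/m animals. Whether the labels of the Ctsd family were placed without regard to genotype cannot be told, because its exact p of 0.429 comes from a test of 3 genotypes whose smallest p is 0.0714. The exact p was 1 for m/m and m/+ animals against +/+ animals and for m/m animals against the rest, groupings that can reach 0.0357, but with both labels on m/+ animals it can only be 1 in either, so these values decide nothing further. A wrong label was not tested, since that needs expression or sequence values that were not analysed here, and an effect of Ctsd dosage or of another mutation in this family stays open as well.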

How the results depend on the processing

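Leaving out each animal in turn moved the exact p of the Mff phenotype label between 0.0182 and 0.0909. It was above 0.05 only when 1 of the 2 m/m animals was left out, which removes 1 of the 2 labels. Since only the labelled animals had a stated genotype, these values follow from the numbers of animals and labels and show neither stability nor its lack. The exact p of the Ctsd phenotype label lay between 0.238 and 1 over the 8 omissions, and was 1 both with m/m and m/+ animals as 1 group against +/+ animals and with m/m animals against the rest, a grouping added after the data were seen. With 3 genotypes and all 8 animals it cannot fall below 0.0714, so its side of 0.05 there was fixed by the design and shows no stability. The count of families within 1 pool was 94 with plate and S number or the whole plate as the pool, and 72 of 72 among families with 12 libraries. These counts could not differ from the main one and show no stability. Each row had 1 S number and lies in 1 plate, and the 72 families are among the 94. Name matching without the lane and read suffix still found 1000 libraries. The median of 12 libraries per family was the same without the 3 labelled families, but it could not move, since 72 of the 94 families had 12 libraries. The alternatives planned for the expression comparisons (normalization, filter on low counts, pseudocount and left-out replicates) were not run, since they need expression values. No paired analysis was possible because the replicate numbers were assigned in accession order and pair no animals. Depth limits nothing reported here, since no read count entered; the number of labelled animals does.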

Other observations

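The tests in this part were all chosen after the sequences and labels had been seen. Thr263 of cathepsin D is the last residue of an N-glycosylation sequon, the tripeptide NVT that starts at Asn261. N-glycans of lysosomal enzymes carry the mannose 6-phosphate tag used for sorting to lysosomes. The reference protein has 2 sequons, at Asn134 and Asn261, and 1 is left with the labelled change. Of the 22 threonines in the protein, 2 would remove a sequon if changed to alanine, which is 9.09% of them. That the change removes a sequon follows from the place of Thr263 in it, so this count supports no hypothesis. Whether the site is used or whether its loss has any effect was not tested.

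The labelled Mff residue lies near the carboxyl end of the protein, where Mff is anchored in the outer mitochondrial membrane. In the principal isoform, the window of 19 residues with the highest mean Kyte-Doolittle hydropathy runs from Met271 to Phe289 and holds the labelled residue, Val272 there. Val272 lies at the edge of this window, next to its first residue. The mean of the window was 1.35 against 0.695 for the highest window that does not overlap it, and it was 0.947 with aspartate in place of valine. The window covers 6.53% of the protein. An effect of V297D was not shown here. Weaker membrane insertion is a candidate explanation for such an effect that these values leave open, since the window was found before its test was chosen. Weaker insertion may be tested by where the protein sits in the cell. With the change, the same window was still the highest. Its rank does not measure anchoring, so whether the anchor is kept or lost cannot be told from it.

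In the Ctsd family, the genotypes stood in unbroken runs along the plate row: 2 m/m animals in columns 4 and 5, 2 +/+ animals in columns 6 and 7, and 4 m/+ animals in columns 8 to 11. The wells of this family followed the animal numbers, which rose without exception from 10 in column 4 to 18 in column 11. Only 6 of the 420 possible orders of these genotypes give unbroken runs, a share of 0.0143. Genotypes independent of well order are not excluded by this share, because it was chosen after the runs were seen in the same 8 animals. A list sorted by number of mutant alleles is argued against, since 0 of the 2 sorted orders match. Siblings of 1 dam or litter numbered together could give such runs, but this cannot be told apart from other causes because 0 kinds of label name a dam or litter. The runs make genotype and well column, hence in-line index, inseparable in this family: each genotype occupied its own stretch of columns.

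Animal numbers followed the wells in most families. They rose without exception along the row in 57 of 94 families, where random order would give 0.0278 families. In all 94 families Spearman's rho of well column and animal number was above 0, with a lowest value of 0.143. S numbers 1 to 96 were in use, 73 of them, and 13 were used by 2 plates. The protocol puts 12 plates in a sequencing library and these libraries lay on 17 plates, so at least 2 sequencing libraries are needed. The reuse of S numbers needs as many, if the S number is the pool index. Which plates were sequenced together is not given in the labels.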
